A study of Mus musculus with 7 samples.

How the data were processed

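Per the labels' protocols, total RNA of 7 samples of MN9D cells was amplified in one cycle, labelled with biotin and hybridised to mouse 430A 2.0 arrays from Affymetrix. The authors deposited log2 expression values made with RMA, per the submitters' processing notes, and the software and its version are not given in the sources used here. RMA subtracts background, makes the arrays' intensity distributions alike and summarises the probes of each probe set, so that a change shared by most transcripts cannot be seen and large folds of bright probe sets are compressed. The deposited log2 values were used as they stood, after a check that the 7 columns had like medians, lay in the range of log2 scanner intensities and were not centred per gene. Scanner files were not used here. An array carries no read depth, and the number of arrays limits the precision. All 7 sample columns were used, and each array took its group from its own label, 4 labelled as overexpressing alpha- and beta-globin and 3 as empty vector. The fourth control array of the design text was not analysed here.

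Of 22690 probe sets, 64 array controls were set aside and 22626 were tested. The platform's annotation gave 1 gene symbol for 20380 of them and several for 691, and 1555 were unnamed here. No gene was named from a probe set with several symbols, except for the globins, where all annotated symbols were given. Symbols were compared with the RefSeq gene table of GRCm38.p6 through Entrez identifiers, and 0 needed updating. The 12393 genes were represented in counts per gene and in list tests by the probe set with the highest mean over all 7 arrays. Of 5800 genes with a changed probe set, 1763 had over 1, and 74 of these had changed probe sets in both directions. Among the named genes this was seen for Mbp. For Prph, Cryab, Cox8a and Nrf1 only a part of the gene's other probe sets passed, in the direction given for the gene.

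The comparison was fitted with limma 3.58.1 in R 4.3.3, with lmFit and eBayes, group as the only term, two-sided tests and Benjamini-Hochberg adjustment over the 22626 probe sets. The fit had 5 residual and 9.10 total degrees of freedom. A probe set was called changed at an adjusted p under 0.05, with no minimum fold, and confidence intervals are at 95%. Gene lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, with separate Benjamini-Hochberg adjustment over the 22 lists and over the 7 lists of cell type markers. The list of globins was counted and not tested. The groups, the fit, the lists, the naming rule and the alternatives, except where said below, were chosen before the data were examined. The named genes were every globin probe set, the 12 genes with the largest rise and the 12 with the largest fall among changed probe sets with 1 symbol whose 4 globin-labelled arrays all lay on one side of the 3 empty vector arrays, up to 4 changed members of each list by smallest p, the dopaminergic genes Th, Ddc, Slc6a3, Slc18a2, Nr4a2 and Pitx3 and 1 further gene that is not reported, and the member of each marker list with the highest mean.

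The fit was tested on simulated data with the spread of the real probe sets, in which 50 probe sets were changed at each of 4 folds. It recovered 54% of the changes of 1.2-fold, 98% of those of 1.5-fold and 100% of those of 2-fold and 4-fold, with 14 calls among unchanged probe sets. Few of the 22626 simulated probe sets were changed and their noise was independent, whereas 39.5% were called in the real data. These shares therefore do not give the recovery or the false calls of the real fit. In simulated lists of 30 genes with independent noise, camera called 0 of 22 unchanged lists and called the list raised by 0.3. The real lists had estimated correlations of up to 0.62 (complex I), so this does not show how often unchanged lists would be called in the real data. Of 5 mouse transcripts with control probe sets at either end, beta-actin and Gapdh were first used to check RNA quality: the 3' minus 5' difference was 0.22 ± 0.01 (SD, n = 3) against 0.21 ± 0.02 (SD, n = 4) for beta-actin (two-sided exact permutation p = 0.914) and -0.27 ± 0.03 against -0.24 ± 0.02 for Gapdh (two-sided exact permutation p = 0.257), where 0.0286 is the smallest p that 35 splits allow. The others were added after the data were seen. For pyruvate carboxylase the difference was -0.32 ± 0.08 against 0.01 ± 0.06 (two-sided exact permutation p = 0.0286, adjusted over the 5 transcripts 0.143). A single transcript could reach no lower adjusted value with 35 splits, so that value does not speak against the difference. For 18S RNA it was 1.19 ± 0.15 against 1.29 ± 0.07 (two-sided exact permutation p = 0.286), and for the transferrin receptor 1.42 ± 0.05 against 1.42 ± 0.10 (two-sided exact permutation p = 0.886).

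Alternatives changed one choice at a time, except that the trend and robust settings of eBayes were changed together and that the replicate block also left out globin-labelled array 4, which has no partner number: centring each array on its median, quantile normalization of the deposited values, removal of the dimmer 50% of probe sets, eBayes with trend and robust settings, array weights, a two-sample test with equal variances, the replicate number as a block, leaving out each array, a fold of at least 1.5, an adjusted p under 0.01, counting genes, camera with an estimated correlation, fry, and the mean of a gene's probe sets. Leaving out empty vector array 1 and globin-labelled array 4 together was added after the data were seen. The label numbers 1 to 3 occur in both groups and were not in the model.

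For neighbouring genes, 12357 genes were put in the order of the GRCm38.p6 gene table, which served only for gene order. Fold changes were limited to 1 log2 unit, genes 20 to 40 places apart were correlated and set against 1000 shuffles of gene order, and running medians over 51 genes were set against 100 shuffles. These settings were chosen once, before their result was seen. Lists of lysosomal, Wnt, Hox, imprinted and keratin genes were written after part of the values had been seen, and the result of each is given.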

Results

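RNA was profiled from MN9D cells, a mouse dopamine-producing line made by fusing embryonic midbrain neurons with neuroblastoma cells, on mouse 430A 2.0 expression arrays from Affymetrix. The labels give 4 arrays from cells overexpressing the alpha and beta chains of hemoglobin and 3 arrays from cells carrying an empty vector. The design text counts 8 hybridised arrays, of which 1 control array failed the submitters' quality assessment and was not used here. The question named in the design text is what globin expression does to these cells, and the comparison of the 2 groups addresses it. The deposited values were RMA expression values on the log2 scale for 22690 probe sets. Array medians lay between 8.90 and 8.94, the lowest values near 3.6 and the highest near 15.1, and the number of arrays limits the precision of every value below. Pairs of arrays within a group correlated at 0.9985 to 0.9990 over the probe sets and pairs across the groups at 0.9903 to 0.9917. The labels do not say that the replicates came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. Changes are given as log2 differences, globin-labelled minus empty vector, and the value after ± is limma's standard error (n = 4 and n = 3 arrays) unless it is named as an SD.

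The signal of 3 alpha-globin probe sets rose in the arrays labelled as overexpressing globin, by 35.8-fold to 142-fold, whereas the signals of the probe sets for beta-globin, the other chain of hemoglobin, differed by 1.26-fold at most. Of 5 adult alpha-globin probe sets, 3 rose, each annotated to both Hba-a1 and Hba-a2. The first went from 7.15 ± 0.34 (SD, n = 3) to 14.30 ± 0.02 (SD, n = 4), a log2 change of 7.15 ± 0.13 and a 142-fold difference (limma adjusted p = 2.03e-09). The others rose by 5.84 ± 0.05 and 5.16 ± 0.08, which are 57.4-fold and 35.8-fold (limma adjusted p = 4.23e-11 and 1.66e-09). On all 3 probe sets every globin-labelled array lay above every empty vector array. Their level in the globin-labelled arrays reached the 99.3rd, 99.6th and 84.0th percentile of all probe sets, so that the first pair stood near the top of the array's range, and their folds are of signal, which is compressed at either end of that range, and not of transcript number. The remaining adult alpha-globin probe sets did not pass, with -0.03 ± 0.05 for that of Hba-a2 alone and 0.03 ± 0.06 for that of Hba-a1 alone.

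Of the 3 adult beta-globin probe sets only 1 of Hbb-b2 passed, with a rise from 6.28 to 6.61, or 0.34 ± 0.07 on the log2 scale and 1.26-fold (limma adjusted p = 0.00558). The probe set annotated to Hbb-bt, Hbb-bs, Hbb-b2 and Hbb-b1 differed by 0.12 ± 0.06, with a 95% confidence interval from -0.02 to 0.26 (limma adjusted p = 0.149). Its 4 globin-labelled arrays lay above the 3 empty vector arrays by a narrow margin (lowest 8.8421, highest 8.8397). Over all 22626 tested probe sets 39.5% passed and 43.5% did not overlap, so neither trait marks out these beta-globin probe sets. The other probe set of Hbb-b2 alone differed by -0.05 ± 0.07. The alpha part of the label was borne out by the probe sets and the beta part was not, and the arrays are called globin-labelled throughout, including wherever a direction is given. Of the 7 embryonic globin probe sets (1 of Hba-x, 6 of Hbb-y and Hbb-bh1), 0 passed in limma, and 0 had an unadjusted p under 0.05 in limma or in the plain two-sample test. The counts of changed adult globin probe sets were the same under both other array scalings tried. In the list of globins and related proteins, 1 of 9 measured genes rose and 1 fell (1 and 1 adjusted over the list alone). That count used only probe sets annotated to a single gene, so it left out the 3 risen alpha-globin probe sets and took Hba-a1 and Hba-a2 from those that did not pass. The member that fell was cytoglobin, Cygb, an oxygen-binding globin of many tissues, by 0.78 ± 0.07 (limma adjusted p = 1.99e-05). Neuroglobin, Ngb, and myoglobin, Mb, did not pass, with 0.13 ± 0.06 and 0.07 ± 0.04.

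**Figure D1:**
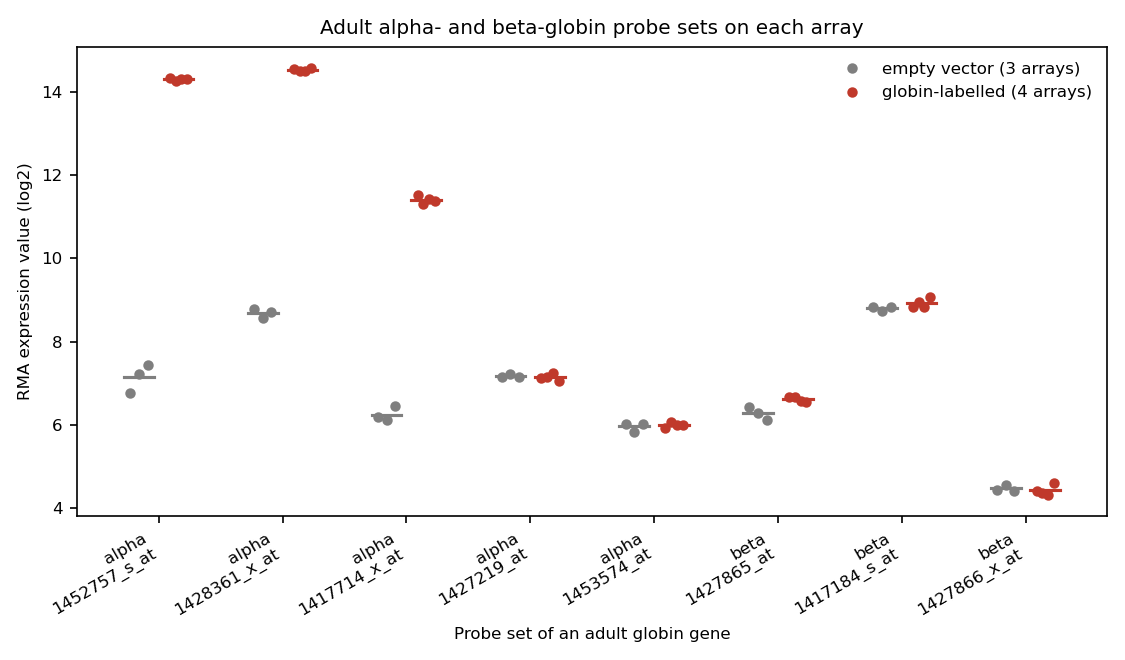
RMA expression values (log2, vertical axis) of the 8 adult globin probe sets (horizontal axis) on each of the 3 empty vector arrays (grey) and 4 globin-labelled arrays (red), with short lines for group means. The 3 alpha-globin probe sets annotated to Hba-a1 and Hba-a2 together separate the groups by 7.15, 5.84 and 5.16, and the beta-globin probe sets by 0.34 at most.

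The groups differed across much of the transcriptome, with the largest changes in genes of varied function. Among the 12 largest rises were Wls, the carrier that takes Wnt proteins to the cell surface, by 3.73 ± 0.07, Dkk1, a secreted Wnt antagonist, by 2.33 ± 0.04 (5.02-fold), and the growth factor gene Bmp7 by 2.95 ± 0.10 (7.74-fold). The matrix genes Tgfbi and Sparc rose by 3.42 ± 0.07 and 2.56 ± 0.10, and Grp, which encodes gastrin-releasing peptide, by 3.29 ± 0.14. Ugt8a, the galactosylceramide synthase, rose by 3.28 ± 0.09, the simple-epithelial keratin gene Krt8 by 3.01 ± 0.06, and the homeobox gene Hoxa9 by 2.47 ± 0.08. For each gene the probe set with the largest change is given, and brighter probe sets of Ugt8a and Hoxa9 rose less, by 0.72 ± 0.08 and 0.29 ± 0.07. Otog, Lix1 and Tram1l1 completed the 12, with rises of 2.92 ± 0.06, 2.66 ± 0.04 and 2.56 ± 0.06.

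Among the falls, Aqp3, a water and glycerol channel, fell by 3.85 ± 0.05 from 9.30 to 5.45. Its other probe sets fell by 2.86 ± 0.08 and fell by 1.98 ± 0.06. Dtna, a dystrophin-associated protein, fell by 3.13 ± 0.07, with 4 of its other 5 probe sets falling less and 1 not passing (-0.18 ± 0.09), and Vegfc, a lymphatic growth factor, fell by 2.82 ± 0.09. The metallothionein gene Mt1 fell by 2.09 ± 0.07 on 1 probe set, while its other probe set differed by -0.10 ± 0.05 and did not pass. Slc4a10, a bicarbonate transporter, fell by 2.07 ± 0.09, Lgals3, which encodes galectin-3, fell by 2.04 ± 0.07, and the imprinted gene Peg10 fell by 2.02 ± 0.08. Abcb1a, a drug efflux pump, fell by 1.96 ± 0.10, Gca fell by 1.94 ± 0.08, and Tha1, a threonine aldolase, fell by 1.88 ± 0.06. Gla, the lysosomal alpha-galactosidase, fell by 1.84 ± 0.18, and Anpep, a cell-surface aminopeptidase, fell by 1.83 ± 0.06. The rule that picked these 24 genes required a call and that the 4 globin-labelled arrays lie on one side of the 3 empty vector arrays. Their limma adjusted p ranged from 3.55e-10 for Aqp3 to 5.63e-05 for Gla. Wls and Ugt8a in the empty vector arrays (5.26 and 4.60) and Dtna in the globin-labelled arrays (4.32) lay below the arrays' 10th percentile of 5.36 to 5.44, and Aqp3 (5.45) lay beside it. Background was not measured there, so their log2 changes and places among the largest are those of dim signal. Stretches of neighbouring genes with a shifted median held 32 of the 141 named genes, among them Dkk1, Tram1l1, Ugt8a, Aqp3 and Tha1.

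**Figure D2:**
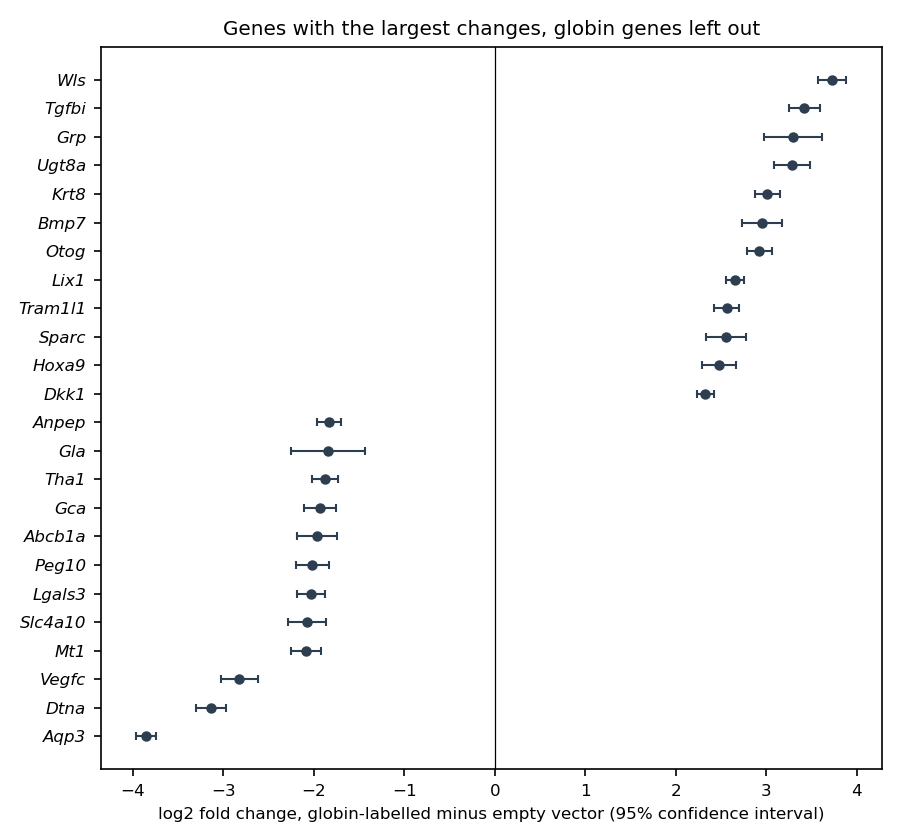
Log2 fold change (horizontal axis, globin-labelled minus empty vector) of the 12 genes with the largest rise and the 12 with the largest fall, globin genes left out, with points for limma's estimate and bars for its 95% confidence interval. The estimates run from 3.73 for Wls to -3.85 for Aqp3, and no interval reaches 0, which follows from picking the genes among changed probe sets.

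Over all 22626 tested probe sets, limma called 8931 changed (39.5%), of which 4131 were higher and 4800 lower in the globin-labelled arrays. Most changes were small, with a median size of 0.30 on the log2 scale among the changed probe sets. A fold of at least 1.5 was reached by 1159 of them (563 higher, 596 lower), a fold of 2 by 300 (179 higher, 121 lower) and a fold of 4 by 43 (35 higher, 8 lower). Counted with 1 probe set per gene, 5043 of 12393 genes changed, 2552 higher and 2491 lower, so that lower calls were the larger part among probe sets and not among genes. The groups did not overlap at 43.5% of the probe sets, where chance gives 5.71%. The first principal component held 81.5% of the variance and separated the groups, and the second held 5.96%, with empty vector array 1 and globin-labelled array 4 at one end. These 2 arrays also had the lowest means of the bacterial hybridisation controls (9.40 and 9.24, others 9.51 to 9.73), a measure whose group means were 9.56 ± 0.14 (SD, n = 3) and 9.50 ± 0.20 (SD, n = 4; two-sided exact permutation p = 0.686). The 3' minus 5' difference of control probe sets differed between the groups for pyruvate carboxylase by 0.33, where the groups did not overlap (two-sided exact permutation p = 0.0286, adjusted over 5 transcripts 0.143), and by 0.10 at most for 4 others. That adjusted value is the lowest a single transcript could reach, so it does not speak against the difference. Without empty vector array 1 and globin-labelled array 4, a choice made after the data were seen, 7375 probe sets were called.

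Genes of the dopaminergic phenotype moved both ways. Th, the rate-limiting enzyme of dopamine synthesis, fell by 0.70 ± 0.05 from 11.78 to 11.08 (limma adjusted p = 1.14e-05), and Ddc, the next enzyme of the pathway, fell by 0.22 ± 0.05 (limma adjusted p = 0.00866). The dopamine transporter gene Slc6a3 and the transcription factor gene Pitx3 did not pass, with 0.04 ± 0.07 and 0.06 ± 0.07. Of the pair of Nr4a2 probe sets, 1 fell by 0.28 ± 0.06 (limma adjusted p = 0.00393) and the other, at -0.13 ± 0.09, did not pass, though it did without empty vector array 1 (-0.26, limma adjusted p = 0.00422). Ret, a receptor for glial cell line-derived neurotrophic factors, rose by 1.64 ± 0.07, Dbh, which turns dopamine into noradrenaline, rose by 0.74 ± 0.07, and the transcription factor gene Foxa1 fell by 0.61 ± 0.07. Of 22 measured members of the dopaminergic list, 4 rose and 3 fell (4 and 3 adjusted over the list alone), and the list as a whole did not pass (median 0.06, camera adjusted p = 0.651). Slc18a2 was not analysed here. Among 30 general neuronal genes 8 rose and 7 fell (9 and 7 adjusted over the list alone), with rises of 0.82 ± 0.06 for Prph and 0.51 ± 0.05 for Ina, intermediate filament genes. In that list Stmn2, a growth-associated microtubule regulator, fell 2.29-fold, from 11.38 to 10.18, and Tubb3, a neuronal tubulin, fell by 0.80 ± 0.06 (camera adjusted p = 0.811).

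Cell cycle genes were higher in the globin-labelled arrays. Of 33 measured genes of the G2 and M phases 26 rose and 1 fell (27 and 1 adjusted over the list alone), with a median of 0.29 and a camera adjusted p = 4.67e-06 (adjusted p = 0.231 with an estimated correlation). Cenpa, the centromeric histone, rose by 0.92 ± 0.06, Ccnb2 rose by 0.50 ± 0.04 and Top2a rose by 0.39 ± 0.04, while Birc5, an inhibitor of apoptosis that also acts at the mitotic spindle, fell by 1.28 ± 0.04. The other probe set of Top2a did not pass. Of 31 S phase genes 22 rose and 3 fell (23 and 3 adjusted over the list alone), with a median of 0.21 and a camera adjusted p = 2.61e-04 (adjusted p = 0.234 with an estimated correlation). The rises included 1.19 ± 0.05 for Ung, a DNA repair glycosylase, 0.75 ± 0.07 for Hells and 0.44 ± 0.04 for Mcm5. Rrm2, a ribonucleotide reductase subunit, rose from 10.62 to 11.62 (limma adjusted p = 1.25e-05). Among 6 histone genes 3 rose and 0 fell (3 and 0 adjusted over the list alone), and 0 were lower at an unadjusted p under 0.05 in limma. H2ax rose by 0.56 ± 0.04, H2az1 by 0.54 ± 0.04 and H2bc22 by 0.28 ± 0.07, the last of which did not pass without empty vector array 2 (limma adjusted p = 0.0600). The histone list did not pass (camera adjusted p = 0.0623), and it did without globin-labelled array 4 (camera adjusted p = 0.0427). Of 21 p53 target genes 3 rose and 7 fell (3 and 7 adjusted over the list alone), a shift that did not pass (median -0.06, camera adjusted p = 0.222). Those that fell included Cdkn1a, the cell cycle inhibitor p21, by 0.37 ± 0.05, Phlda3 by 0.55 ± 0.05, Perp by 0.52 ± 0.05 and Apaf1 by 0.39 ± 0.05.

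Genes of energy metabolism rose in part. Of 34 nuclear-encoded genes of mitochondrial complex I, the NADH dehydrogenase, 16 rose and 1 fell (16 and 1 adjusted over the list alone), with a median of 0.14 and a camera adjusted p = 0.00517 (adjusted p = 0.894 with an estimated correlation). Ndufv3 rose by 0.52 ± 0.05, Ndufb8 by 0.45 ± 0.04 and Ndufa9 by 0.34 ± 0.04, and the assembly factor gene Ndufaf1 fell by 0.49 ± 0.05. Of 16 glycolysis genes 10 rose and 2 fell (10 and 2 adjusted over the list alone), with a median of 0.21 and a camera adjusted p = 0.00909 (adjusted p = 0.350 with an estimated correlation). Aldoc, an aldolase, rose by 1.46 ± 0.05, Slc16a3, a lactate exporter, by 1.09 ± 0.07, and the phosphofructokinase genes Pfkl and Pfkm by 0.77 ± 0.04 and 0.64 ± 0.04. Genes of complexes II to V moved both ways, with 11 of 44 higher and 9 lower (12 and 9 adjusted over the list alone; median 0.03, camera adjusted p = 0.811). Cox8a and Surf1 rose by 0.41 ± 0.04 and 0.39 ± 0.05, while Uqcrh fell by 0.59 ± 0.04 and Sco2 fell by 0.56 ± 0.06. Of 41 genes of the mitochondrial ribosome, import and biogenesis 12 rose and 6 fell (12 and 6 adjusted over the list alone; camera adjusted p = 0.503), with 0.53 ± 0.05 for the nuclear receptor gene Esrra, 0.37 ± 0.05 for Mrps28, 0.36 ± 0.06 for Nrf1 and -0.39 ± 0.05 for Mrps7. Hypoxia-response genes divided evenly, with 10 of 32 higher and 9 lower (10 and 10 adjusted over the list alone). Egln3, an oxygen-sensing prolyl hydroxylase, rose by 0.85 ± 0.05, Ero1a by 0.58 ± 0.04 and Car12 by 0.45 ± 0.05, and Adm fell by 0.81 ± 0.05. The median of the hypoxia list was -0.00, its mean 0.04 and camera's direction upward, which did not pass (camera adjusted p = 0.891), and the sign of the median turned under both other array scalings.

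Antioxidant, nitric oxide and iron genes moved both ways. Mt2, which encodes a metallothionein like Mt1, fell by 1.63 ± 0.05, whereas Ephx1, an epoxide hydrolase, and Gstm1, a glutathione transferase, rose by 0.72 ± 0.05 and 0.67 ± 0.05. Of 35 antioxidant genes 9 rose and 10 fell (9 and 11 adjusted over the list alone; camera adjusted p = 0.651). Nos1, the neuronal nitric oxide synthase, rose by 2.31 ± 0.10, from 9.23 to 11.54, and the cGMP-dependent kinase genes Prkg2 and Prkg1 rose by 1.51 ± 0.08 and 0.87 ± 0.07, though a second Prkg2 probe set did not pass (0.17 ± 0.08). Adh5, which reduces S-nitrosoglutathione, rose by 0.43 ± 0.04. Of 22 nitric oxide genes 5 rose and 3 fell (5 and 3 adjusted over the list alone), with a median of -0.02, a mean of 0.18 and an upward camera direction that did not pass (camera adjusted p = 0.811). Of 32 genes of iron and heme handling 6 rose and 10 fell (7 and 11 adjusted over the list alone; median -0.04, camera adjusted p = 0.389). Slc25a37, the mitochondrial iron importer, and Fth1, the ferritin heavy chain, rose by 0.43 ± 0.05 and 0.39 ± 0.04, while the heme exporter gene Flvcr1 fell by 0.51 ± 0.05 and the iron-sulphur cluster gene Nfs1 fell by 0.40 ± 0.04.

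Interferon-response genes were lower in the globin-labelled arrays. Of 29 measured members 15 fell and 4 rose (16 and 5 adjusted over the list alone), with a median of -0.18 and a camera adjusted p = 4.79e-04 (adjusted p = 0.179 with an estimated correlation). Oasl2 fell by 1.65 ± 0.05, Usp18, which restrains interferon signalling, fell by 1.06 ± 0.06, Rtp4 fell by 1.04 ± 0.07, and B2m, the light chain of class I histocompatibility molecules, fell by 0.75 ± 0.04. The other probe set of Rtp4 did not pass.

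Extracellular matrix and adhesion genes and cholesterol synthesis genes were higher. Of 38 matrix and adhesion genes 14 rose and 3 fell (14 and 3 adjusted over the list alone), with a median of 0.12 and a camera adjusted p = 0.0202 (adjusted p = 0.231 with an estimated correlation). Sparc rose by 2.30 ± 0.05 on the probe set with its highest mean, the laminin receptor subunit gene Itga6 by 0.76 ± 0.04, Fbln1 by 0.73 ± 0.05 and the fibronectin gene Fn1 by 0.66 ± 0.05. Fibroblast markers moved with them only in part: 2 of 11 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.885). As fixed, the fibroblast and matrix lists share Col1a1, Col1a2, Col3a1, Dcn, Lum and Fbn1, so they are not separate. Thy1 rose by 1.94 ± 0.06 and Pdgfrb by 0.96 ± 0.06, while S100a4 fell by 0.31 ± 0.06. The abundant fibroblast collagens did not pass, with 0.10 ± 0.05 for Col1a1, -0.04 ± 0.05 for Col1a2 and 0.03 ± 0.06 for Col3a1, which were named after their values were seen. Of 19 cholesterol synthesis genes 11 rose and 2 fell (13 and 2 adjusted over the list alone), with a median of 0.17 and a camera adjusted p = 0.0117 (adjusted p = 0.231 with an estimated correlation). Tm7sf2 rose by 0.86 ± 0.06, Msmo1 by 0.52 ± 0.06, Fdps by 0.46 ± 0.05 and Sqle by 0.35 ± 0.04.

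Genes of the unfolded protein and integrated stress responses were higher at the preset correlation, and heat shock genes moved both ways. Of 38 genes of the former list 16 rose and 6 fell (16 and 7 adjusted over the list alone), with a median of 0.09 and a camera adjusted p = 0.0443 (adjusted p = 0.435 with an estimated correlation). The serine pathway genes Phgdh and Shmt2 rose by 0.38 ± 0.05 and 0.36 ± 0.04, the ATF4 target Trib3 rose by 0.33 ± 0.04, and the chaperone gene Pdia3 fell by 0.35 ± 0.04. This list did not pass without empty vector array 1 (camera adjusted p = 0.0510) or without globin-labelled array 1, 2 or 3 (camera adjusted p = 0.0760, 0.0519 and 0.0517). Of 20 heat shock genes 6 rose and 5 fell (6 and 5 adjusted over the list alone), with 1.43 ± 0.09 for Hspa1b, 0.84 ± 0.06 for Stip1, -0.68 ± 0.07 for Cryab and -0.42 ± 0.04 for Hspb8. Their median was -0.01, their mean 0.08 and camera's direction downward, which did not pass (camera adjusted p = 0.960), and the sign of the median turned when arrays were centred. Of 32 proteasome genes 11 rose and 4 fell (12 and 4 adjusted over the list alone; camera adjusted p = 0.396), with 0.30 ± 0.04 for Psmb3, -0.29 ± 0.04 for Psmc5, -0.27 ± 0.05 for Psmb10 and -0.19 ± 0.04 for Psmd12. Of 30 ribosomal protein genes 0 rose and 2 fell (0 and 1 adjusted over the list alone; camera adjusted p = 0.503), with -0.56 ± 0.04 for Rps6 and -0.14 ± 0.04 for Rpl38, and 2 were higher at an unadjusted p under 0.05 in limma. The Rps6 probe set lay at 10.11 in the empty vector arrays, below the list's median level of 14.57, and the gene's other probe set did not pass. Rpl38 was not called with the replicate number as a block (limma adjusted p = 0.130) or without empty vector array 1 and globin-labelled array 4 together (limma adjusted p = 0.0638). The plain two-sample test with Benjamini-Hochberg adjustment called 4 ribosomal protein genes higher. Immediate early genes moved both ways, with 8 of 22 higher and 6 lower (9 and 9 adjusted over the list alone; camera adjusted p = 0.960). Egr1 and Dusp6, which follow growth factor signalling, rose by 1.43 ± 0.05 and 0.73 ± 0.04, while Klf6 fell by 0.89 ± 0.07 and Dusp1 fell by 0.61 ± 0.05.

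**Figure D3:**
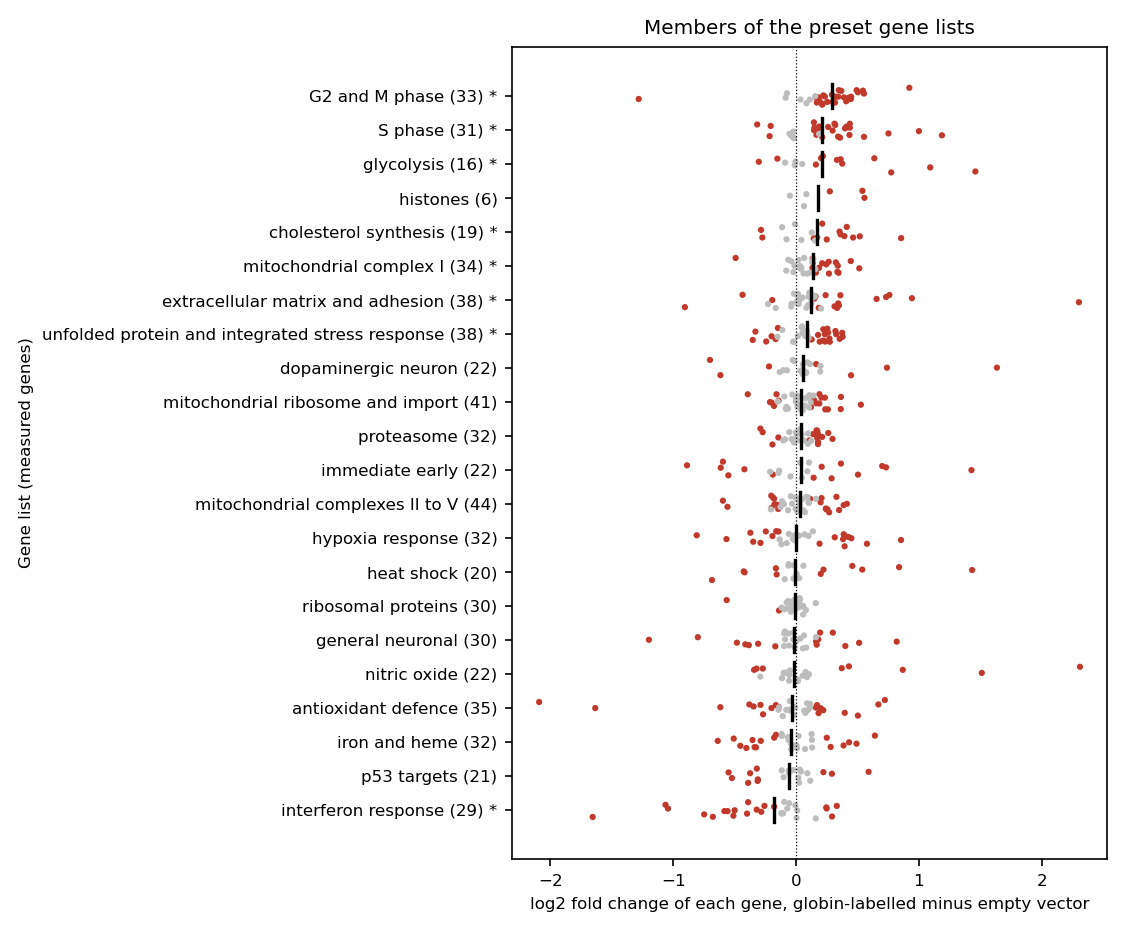
Log2 fold changes (horizontal axis, globin-labelled minus empty vector) of the measured genes of the 22 lists (vertical axis, number of measured genes in brackets), red where limma's adjusted p was under 0.05 and grey otherwise, with black lines for medians and asterisks for the 8 lists with a camera adjusted p under 0.05 at the preset correlation. The medians run from 0.29 for the G2 and M phase genes to -0.18 for the interferon-response genes.

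Markers of cell types that the cultures might hold or resemble showed no shift as lists at the preset correlation (0 of 7 lists in camera, 0 at an unadjusted p under 0.05). The neural crest and sympathetic list had 3 of 8 genes higher and 2 lower (4 and 2 adjusted over the list alone), with rises of 1.03 ± 0.06 for the nicotinic receptor gene Chrna3 and 0.74 ± 0.07 for Dbh and falls of Gata2 by 0.40 ± 0.04 and Gata3 by 0.35 ± 0.05. Its member with the highest mean, Phox2a, rose by 0.16 ± 0.05 (limma adjusted p = 0.0420), and it was not called without empty vector array 1 or 2 (limma adjusted p = 0.114 and 0.0624) or without globin-labelled array 1, 2, 3 or 4 (limma adjusted p = 0.0845, 0.0963, 0.0650 and 0.0681). Among 14 erythroid markers 2 rose and 3 fell (2 and 3 adjusted over the list alone), with falls of Tal1 by 0.45 ± 0.06, Rhd by 0.41 ± 0.05 and Trim10 by 0.41 ± 0.07. The anion exchanger gene Slc4a1 rose by 0.29 ± 0.08, which was not called without empty vector array 1 or 2 or globin-labelled array 2 (limma adjusted p = 0.0843, 0.0860 and 0.0518). The other 2 probe sets of Slc4a1 did not pass. The erythroid median was 0.07 and the mean -0.02, with a downward camera direction (camera adjusted p = 0.885). Of 13 microglia markers 1 rose and 1 fell (0 and 1 adjusted over the list alone), and Cd68, a lysosomal membrane protein, fell by 1.25 ± 0.09. The riser, Tyrobp, at 0.19 ± 0.06 (limma adjusted p = 0.0367), was not called without empty vector array 1 or 2 or globin-labelled array 2 or 3 (limma adjusted p = 0.0873, 0.137, 0.0923 and 0.0894). Laptm5, at -0.18 ± 0.07 on its brightest probe set, did not pass (limma adjusted p = 0.0593). That probe set did pass without empty vector array 1 (limma adjusted p = 0.0466) and without globin-labelled array 1 (limma adjusted p = 0.0465). The other 2 probe sets of Laptm5, not used in the list count, were both called lower with all arrays. Among 11 oligodendrocyte markers 1 rose and 1 fell (1 and 1 adjusted over the list alone), with Ugt8a higher by 0.72 ± 0.08 on its brighter probe set and Mbp lower on its brightest (-0.70 ± 0.06). Of the other 7 Mbp probe sets, 4 also fell and 1 rose, by 0.28 ± 0.05, and Cnp did not pass (-0.06 ± 0.04). Among 11 astrocyte markers 1 rose and 1 fell (1 and 1 adjusted over the list alone), Glul by 0.20 ± 0.05 and Fabp7 with -0.30 ± 0.08, which was not called without empty vector array 3 (limma adjusted p = 0.0592). Glul was not called with the replicate number as a block (limma adjusted p = 0.0624) or without empty vector array 1 and globin-labelled array 4 together (limma adjusted p = 0.0592). The other probe set of Glul did not pass. Of 10 endothelial markers 0 rose and 2 fell (0 and 2 adjusted over the list alone), Esam by 0.32 ± 0.06 and Kdr by 0.27 ± 0.08, and 0 were higher at an unadjusted p under 0.05 in limma, while the list's median was 0.04 and its mean -0.02. Kdr was not called without empty vector array 1 or 2 or globin-labelled array 3 (limma adjusted p = 0.0849, 0.0648 and 0.0627), and Flt1 did not pass (0.07 ± 0.06).

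The list calls rest on a preset correlation between genes of 0.01, and with a correlation estimated from the 5 residual degrees of freedom 0 of the 22 lists passed in camera, 4 of them having an unadjusted p under 0.05, whereas fry called 17. For Peg10, Rrm2, Birc5, Trib3, Phgdh, Gstm1, Psmb3 and Gata2, 1 of the 4 globin-labelled arrays stood apart from the other 3, with all 4 still on one side of the empty vector arrays.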

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

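The test of control probe sets was chosen after the result of the main comparison was seen. Of 151 named probe sets, 10 had 1 globin-labelled array far from the other 3, or 6.62%, where chance gives about 5%. These were found by comparing the gap to the nearest array with the whole range of the 4 arrays, and the 3 empty vector arrays were too few for that comparison. Array 4 was the distant one for Peg10 (6.59, where the others averaged 6.29), Gata2 (11.73 against 11.61), Birc5 (10.83 against 10.92), Phgdh (13.11 against 13.16) and Psmb3 (12.77 against 12.89). Array 1 was the distant one for Rrm2 (11.49 against 11.66), Trib3 (13.38 against 13.30) and Gstm1 (11.45 against 11.38). Array 3 was the distant one for Hbb-y on 1 probe set (3.93 against 4.12) and for Hbb-bh1 on 1 probe set (6.32 against 6.23), where the other 3 arrays held exactly equal values.

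Among control probe sets, which lie outside the comparison of the groups, 3 of the 19 for mouse sequences were higher in the globin-labelled arrays. Those for pyruvate carboxylase rose by 0.43 (middle part, MB) and 0.47 (3' end), and that named MURINE_b1 rose by 0.35 (limma adjusted p = 1.87e-04, 5.74e-04 and 5.54e-04 over the 64 control probe sets).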

How the results depend on the processing

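The alternative without empty vector array 1 and globin-labelled array 4 was chosen after the data were seen. The count of 8931 changed probe sets lay between 7803 and 8271 when single arrays were left out, at 7375 without those 2 arrays, and between 6337 and 9224 under the other alternatives that kept the threshold and counted probe sets. It became 1159 with a fold of at least 1.5 and 5043 when counted per gene, each of which follows from how the count is made. No probe set called in both an alternative and the reported fit changed direction, and the share of higher calls lay between 44.2% and 48.6% under the alternative scalings, filter, fits and sets of arrays, and at 50.6% when counted per gene. All 24 genes of largest change passed under each alternative fit except the removal of the dimmer 50% of probe sets, under which 7 were left and passed, the others having been removed. The fold of at least 1.5 and the adjusted p under 0.01 were not applied to single named probe sets, and that of Psmb3, for one, at 1.23-fold would lose its call. Of 151 named probe sets 11 gained or lost a call under any of the other alternatives (those of H2bc22, Slc4a1, Fabp7, Cnp, Tyrobp, Kdr, Phox2a, Rpl38, Glul and Laptm5 and 1 of Nr4a2), and none turned. The two-sample test ended those of H2bc22, Slc4a1, Fabp7, Tyrobp, Kdr and Phox2a and called Cnp, quantile normalization ended that of Tyrobp, the block those of Rpl38, Glul, Tyrobp and Phox2a, and leaving out the 2 arrays those of Rpl38, Slc4a1, Glul, Tyrobp, Kdr and Phox2a, while it called Laptm5 and Nr4a2. The label numbers did not pair the arrays: the deviations of same-numbered arrays correlated at -0.36, -0.30 and -0.14. With the replicate number as a block 6337 probe sets were called, against 8031 on the same 6 arrays without it. The histone list passed with the block (camera adjusted p = 0.0498) and also on these 6 arrays, without globin-labelled array 4, with no block (0.0427).

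With an estimated correlation 0 lists passed in camera, the adjusted p being 0.894 for complex I, 0.350 for glycolysis, 0.234 for S phase, 0.231 for G2 and M phase, cholesterol synthesis and matrix, 0.435 for the unfolded protein and integrated stress response and 0.179 for interferon. The same 5 residual degrees of freedom give that estimate. The stress response list gave 0.0983 with the mean of a gene's probe sets and 0.0326 to 0.0760 with single arrays left out. The histone list passed at 0.0427 with quantile normalization, 0.0455 with trend and robust settings and 0.0477 with the two-sample test, and ran from 0.0427 to 0.0893 with single arrays left out. The cause was not tested. fry, which asks whether a list's genes move on balance one way and not whether they differ from other genes, called 17 lists. Those not called by camera were hypoxia (0.00689), iron and heme (0.00311), nitric oxide (0.00367), dopaminergic (0.0229), p53 (6.18e-04), ribosomal (0.0229), proteasome (0.0333), histones (1.86e-04) and heat shock (0.00121, upward, the reverse of camera's direction), and the fibroblast (8.09e-04) and sympathetic markers (0.00255). A turn of direction in a list uncalled under both settings was not counted. Signal near the background limits dim probe sets such as those of the embryonic globins.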

Other observations

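The lists of lysosomal, Wnt, Hox, imprinted and keratin genes, the linkage groups and the region from Col22a1 to Krt6b were chosen after values were seen, as were the tests of control probe sets, of swapped arrays, of a wrong group label, of probe set position and of fibroblast markers, while the tests of other splits and of neighbouring genes were set beforehand. Lysosomal genes were lower in the globin-labelled arrays. Of 43 measured lysosomal genes 32 fell and 4 rose, with a median of -0.29 and a camera adjusted p = 1.31e-10 over the 5 lists (adjusted p = 0.00254 with an estimated correlation). Gla fell by 1.83 ± 0.07 on its brightest probe set, Gpnmb by 1.53 ± 0.08, and the cathepsin gene Ctsb by 0.75 ± 0.04, while Ctsf and Sgsh rose by 0.36 ± 0.05 and 0.37 ± 0.06. Without the members whose values had been seen when the list was written, 27 of 38 fell and 4 rose (camera adjusted p = 2.91e-08, adjusted p = 0.00518 with an estimated correlation). The list was tested on the arrays that prompted it and stays a hypothesis for other samples.

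Of 44 Wnt signalling genes 15 rose and 3 fell, with a median of 0.11 and a camera adjusted p = 6.56e-04 (adjusted p = 0.0182 with an estimated correlation). Beside Wls and Dkk1, the cyclin gene Ccnd2 rose by 1.99 ± 0.05, Sfrp2, a secreted Wnt-binding protein, by 1.69 ± 0.10, and the receptor gene Fzd7 by 1.24 ± 0.04, while Wnt3 fell by 0.67 ± 0.10. Without the members already seen, 12 of 41 rose and 3 fell (camera adjusted p = 0.0121, adjusted p = 0.0517 with an estimated correlation). Hox genes (9 of 31 higher, 1 lower, camera adjusted p = 0.0508), imprinted genes (10 of 28 higher, 5 lower, camera adjusted p = 0.324) and keratin and junction genes (3 of 21 higher, 3 lower, camera adjusted p = 0.398) did not pass.

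Genes that lie near each other moved together in places. In 27 overlapping stretches the running median lay beyond that of 100 shuffles, and these held 757 of the 5040 called genes and 1313 of the 12357 placed genes. The region from Col22a1 to Krt6b in the GRCm38.p6 gene order, joined from several of these stretches, held 302 genes with a median of 0.17, of which 154 were called higher and 10 lower, and 84.4% had a positive change. It lies in the linkage group from Selenop to Mucl2, of whose other 193 genes 58 were higher and 13 lower, with a median of 0.06 and 73.1% positive, so the region is not sharply bounded. From Pars2 to Dph2, 44 of 84 genes were lower and 8 higher, with a median of -0.24, and from Sox9 to Card14, a stretch that holds Cygb, Birc5 and Tha1, 44 of 86 were lower and 14 higher. Birc5 and Tha1 also lie in the overlapping stretch from Tmc6 to Csnk1d, where 28 of 58 were higher and 10 lower, with a median of 0.14, opposite to their falls. Over whole linkage groups, those from Selenop to Mucl2 and from Ighmbp2 to Csf2ra had medians of 0.12 and 0.12, and those from Crem to Rttn and from Cd99 to Samd11 had -0.06 and -0.02, all beyond the range of 1000 shuffles (-0.02 to 0.05), the last by less than the rounding shows.

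That 39.5% of probe sets were called is the first pattern. Of the 35 splits of the 7 arrays into 3 and 4, only 1, the real one, gave as many changed probe sets (8931, against 0 for every other split in limma and in the two-sample test, and up to 6052 at an unadjusted p under 0.05). This argues against a random division of these arrays as the source, with 0.0286 as the smallest exact permutation p that 35 splits allow. It does not argue against a chance difference between cultures, since the spread between the arrays may be technical. Every other split mixes the groups and so widens the spread within its sides, and the gap between 8931 and 0 carries no further weight. The foreign control probe sets showed no large difference left in the deposited values, as 0 of 45 changed in limma, with 0 at an unadjusted p under 0.05. They were read after RMA had made the arrays' intensity distributions alike. They therefore cannot decide whether array scaling or hybridisation strength differed before that step. Most of the 45 lay lower in the globin-labelled arrays, and the largest difference was -0.20 ± 0.13. A small shared shift is therefore not excluded, and most of the called changes were themselves small, with a median size of 0.30. Fold changes of genes 20 to 40 places apart correlated at 0.0634, above the highest of 1000 shuffles (0.00700). A contrast within the globin-labelled arrays gave 0.00935, which is lower but also above every shuffle of the changes between the groups. The values of this contrast were not themselves shuffled. Exceeding the shuffles is therefore not taken by itself to point to a difference between the populations. Gains or losses of chromosome segments that differ between the cell populations may account for a part, but they are not shown by this. Regional co-expression and base composition stay open, as do the globins and any other difference between the populations.

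The second pattern is the strong rise of alpha-globin beside a small rise or none of beta-globin. Arrays swapped between the groups are argued against, since the lowest globin-labelled array lay at least 4.87 above the highest empty vector array on each of the 3 risen alpha-globin probe sets. Probe sets that do not read the part of the gene carried by the construct could hide beta-globin, because 2 adult alpha-globin probe sets also did not rise while 3 did. With no sequence of the construct or the probes used here, that, a low level of beta-globin transcripts and a label that is wrong for the whole group, such as cells with alpha-globin alone, cannot be told apart, the largest change of an adult beta-globin probe set being 0.34.

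The third pattern is the rise in the matrix and adhesion list (14 of 38 higher, 3 lower), beside which Thy1 and Pdgfrb of the fibroblast markers rose. The matrix and fibroblast lists share Col1a1, Col1a2, Col3a1, Dcn, Lum and Fbn1. Fibroblasts in the globin-labelled cultures are argued against by the upper quartile of the fibroblast markers, 0.0974 over 11 genes, since fibroblasts would bring their abundant collagens. That quartile leaves out the rises of Thy1 and Pdgfrb, with which the list's mean was 0.26 and fry called the list upward (fry adjusted p = 8.09e-04). Col1a1 stood at 6.22 and 6.32, Col1a2 at 6.56 and 6.52 and Col3a1 at 5.24 and 5.27 in the empty vector and globin-labelled arrays. A change within the MN9D cells, through the globins or through another difference between the populations, stays open and was not tested.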
